A study of Homo sapiens with 8 samples.

How the data were processed

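The 8 samples are total RNA libraries of MCF10A cells, 2 in each of the groups DMSO, AZD6738, IR and AZD6738+IR, and each sample was placed in its group from the treatment given in the labels. Per the labels' protocols, ribosomal RNA was depleted, libraries were stranded and 75 bp were read from both ends. Per the submitters' processing notes, FastQC, HISAT2 2.0.4 and StringTie 1.3.4d were used with the genome build hg38, and the roles and settings of these tools are not given in the sources used here. The authors deposited 1 filtered table with a value per locus and library, and its filter is not given in the sources used here. Per the file headers the table names no unit. The deposited values were taken as FPKM, fragments scaled to transcript length and library total, because StringTie writes FPKM and TPM, the column totals differ between libraries, and the values are fractional. A filtered table of TPM would also have these features, so the unit is an assumption. TPM of the same run would differ by 1 factor per library, which the scaling alternatives below cover. FPKM adjusts each value for transcript length and library total, so a few very abundant RNAs can shift all other values of a library, and neither depth nor counting error can be recovered from it. The authors also deposited a p-value and an adjusted p-value per locus without naming the comparison, and 100% of the p-values equalled an F test over the 4 groups on the untransformed values within a relative tolerance of 1e-06. These p-values were not used further.

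The table held 14944 loci, 9762 with a gene symbol and 5182 named only as assembled loci. Where a symbol had several entries, as for 217 symbols, the entry with the highest mean was kept and 299 were left out, which gave 14645 loci, 9463 of them named. Assembled loci can merge neighbouring genes, and the deposited values do not say how reads shared by near-identical copies were assigned. Columns were matched to groups by name. Within a group the columns carry the letters A and B whereas the labels number the replicates, so a library is known by its letter only. No replicate pair held identical values, and there were 0 value columns of no sample.

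The main test, fixed before the data were examined, was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 coefficient for each group in a single fit of all 8 libraries, an intensity trend in the variance, and loci with a mean of at least 1 FPKM over all libraries. This left 12809 loci, 8666 of them named, 4 residual degrees of freedom and 1.79 prior degrees of freedom. There were 6 contrasts: AZD6738 against DMSO, IR against DMSO, AZD6738+IR against each of the other groups, and the interaction, which is AZD6738+IR minus AZD6738 minus IR plus DMSO. All tests were two-sided, and a locus was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast.

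In the same fit 18 gene lists written before the data were examined were tested with camera at a preset correlation of 0.01, with adjustment over the lists of a contrast, then with the correlation estimated from the residuals, and with fry. Camera compares a list with all other loci. They cover interferon-stimulated genes, cytosolic nucleic acid sensing, interferons and their receptors, antigen presentation, p53 targets, DNA replication and G1/S, G2/M and mitosis, the ATR pathway and DNA damage response, NF-kB targets and inflammatory secreted factors, replication-dependent histones, basal and luminal epithelium, squamous differentiation, mesenchymal and blood cell markers, cholesterol synthesis, the integrated stress and unfolded protein responses, ribosomal proteins, and mitochondrially encoded genes. Of these, 16 had at least 5 tested members. The blood and immune cell list had fewer and the mitochondrial list none, so the latter has no result, and members without a matching symbol in the table were not analysed under their names. Loci named only as assembled loci may include some of these members. Those without a match included IFI44L, IFIT2, OAS2, STAT2 and IRF9 of the interferon-stimulated genes. A call lost with the estimated correlation need not mean that the members of a list were correlated. With it camera takes its p-value from the 4 residual degrees of freedom, whereas at the preset correlation it uses far more. For IR against DMSO, p53 targets had an estimated correlation of 0, below the preset 0.01, yet camera adjusted p went from 4.01e-08 to 0.0596.

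Named genes were chosen by a rule fixed before the data were examined. For each contrast these were up to 6 named genes with the largest rise and 6 with the largest fall among those past the threshold, with a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups (not required for the interaction), up to 4 called members of each list, and 19 sentinel genes of which 17 were found by symbol. The sentinels without a matching symbol in the table were RIGI (DDX58) and MAVS. Genes of a contrast that the text adds in other contrasts were named by the rule in at least 1 of them. FUCA1 was named because it was the only exception of its list, and this was chosen after its values were seen. Some genes that the rule names are not reported here. A ratio of group means is given where both means were at least 0.5 FPKM. Gene positions come from the GENCODE annotation of the same assembly.

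The fit, the list test and the random lists used in the closing part were tested on simulated data: libraries drawn from the real means and residual spread of the 12809 loci, with 67 loci changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold in each simulated comparison, and a further list shifted as a block, which made 230 changed loci. For IR against DMSO, 68.7% of loci changed 1.5-fold, 88.1% of those changed 2-fold and 95.5% of those changed 4-fold were recovered. For the interaction these shares were 61.2%, 85.1% and 93.9%. For AZD6738 against DMSO they were 74.6%, 89.6% and 95.5%. Of called loci, 5.97% were false for IR against DMSO, 5.69% for AZD6738+IR against IR and 5.38% for the interaction, against the nominal 5%, and 4.02%, 4.35% and 3.86% for AZD6738 against DMSO and AZD6738+IR against AZD6738 and DMSO. Each comparison was simulated once, with the same mean and spread of a locus in every group. Differences in these shares between comparisons of 2 groups therefore reflect the draw. Camera p was 0.547 or higher for a list of unchanged loci and 5.6e-38 or lower for the shifted list. Random lists placed these at percentiles 7.23 to 85.4 and at 100. Simulated loci varied independently, so correlation between genes was not tested. The loci changed by these folds all had a mean log value above that of 5 FPKM, and the folds were added on the log2(FPKM + 1) scale. The shares recovered therefore do not cover loci with lower levels, where the added 1 shrinks a change of FPKM. Only 230 of 12809 loci were changed, whereas 61.8% were called for IR against DMSO in the real data. Shares recovered and false depend on how many loci change, so they need not hold for the comparisons with irradiation.

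Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, log values centred on each library's median, quantile normalization, no intensity trend, only the groups compared, an absolute log2 fold change of at least 1, an estimated correlation, and each library left out in turn. Chosen after the data were seen were keeping every entry of a repeated symbol, scaling libraries to equal totals outside the 4 most abundant loci, named loci alone, and a fit with the library letter as a block. Transcript lengths for 98.7% of named loci came from GENCODE transcripts. Random lists of the closing part were 10000 per list, each member replaced by 1 of the 100 nearest named loci outside the gene lists in abundance, or in abundance and length. No limit was set on how far these loci lay from the member. Camera was also run on these lists, adjusted over the 3 of them, which was chosen after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for preparation and figures.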

Results

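MCF10A is an immortalised, non-tumorigenic line of human breast epithelial cells. Total RNA depleted of ribosomal RNA was sequenced in 4 groups of 2 libraries each: cells given the solvent DMSO, cells given 250 nM AZD6738 (an inhibitor of ATR, the kinase that responds to stalled replication forks and resected DNA breaks), cells irradiated with 20 Gy (IR), and cells given both (AZD6738+IR). Solvent or inhibitor went on 2 hours ahead of the irradiation, and the treatment lasted 3 days. The series title puts the question as whether blocking ATR enlarges the interferon response to ionizing radiation and how sensors of cytosolic nucleic acids take part. The table names no unit and its values were taken as FPKM, so the number of reads behind a value is unknown and no counting interval could be attached to it. The FPKM values of a library, summed over all loci, were lowest in AZD6738 B at 864305.7 and highest in AZD6738+IR B at 969381.1. The 4 most abundant loci took 53.27% to 54.12% of the total in the 4 libraries without irradiation, 56.48% and 56.71% in the IR libraries, and 57.05% and 61.42% in the AZD6738+IR libraries, where library B stood apart from library A. Libraries are named A and B as in the deposited columns. The labels do not say that libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical. Unless stated otherwise, levels are group means ± SD with n = 2, folds are ratios of those means, and log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low levels. The interaction can also be overstated on this scale, where an effect from low levels is understated more than the one it is compared with.

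Irradiated and non-irradiated libraries separated on the first principal component, which held 66.3% of the variance of the log values. DMSO and AZD6738 libraries lay between -43.43 and -38.18 on it, IR libraries at 15.83 and 16.62, and AZD6738+IR libraries at 63.85 and 66.1. The second component held 11.9% and set the IR libraries apart from the other three groups.

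**Figure D1:**
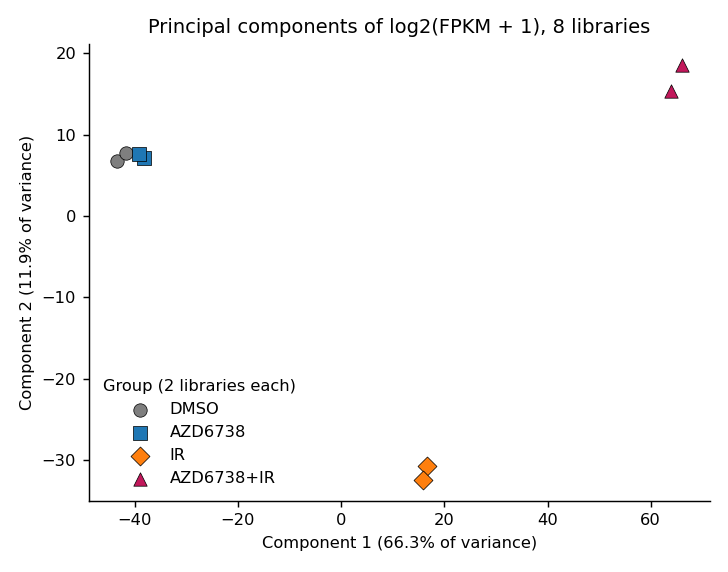
Scores of the 8 libraries on the first and second principal components of log2(FPKM + 1), without units, with 1 point per library and colour and shape by group. DMSO and AZD6738 libraries lie between -43.43 and -38.18 on component 1, and the AZD6738+IR libraries lie farthest along component 1, at 63.85 and 66.1.

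Irradiation alone was compared with DMSO to give the response to radiation without the inhibitor. Most interferon-stimulated genes, p53 targets, inflammatory secreted factors and genes of squamous differentiation rose, while most cell cycle and histone genes fell. No list of this comparison passed camera with an estimated correlation, where the lowest adjusted p = 0.0596. That value belonged to the p53 targets, whose estimated correlation was 0, so correlation between members does not account for that loss. CDKN1A (chromosome 6, 36676460 to 36687339, hg38), the p21 inhibitor of cyclin-dependent kinases, rose 5.58-fold, from 54.1 ± 1.5 to 302 ± 11 FPKM. ISG15 (chromosome 1, 1001138 to 1014540), a ubiquitin-like protein induced by interferon, rose 12.9-fold, from 2.49 ± 0.7 to 32.2 ± 5.1 FPKM. S100A7 (chromosome 1, 153457744 to 153460701), the antimicrobial protein psoriasin of stressed squamous epithelium, rose 70.3-fold, from 2.32 ± 0.11 to 163 ± 30 FPKM. ASNS (chromosome 7, 97852118 to 97872542), asparagine synthetase, fell 8.02-fold, from 82.2 ± 3.8 to 10.3 ± 2 FPKM.

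Interferon-stimulated genes rose together after irradiation: 27 of the 29 tested members passed the genome-wide threshold and none fell, with 28 higher when adjusted over the list alone. Their median log2 fold change was 0.97, and the list ranked above the other loci with camera adjusted p = 1.65e-13, and with adjusted p = 0.122 with an estimated correlation. IFI6 rose from 2.72 ± 0.56 to 41.8 ± 2.9 FPKM and IFI27 from 0.849 ± 0.088 to 14.5 ± 0.86. IFIT1, which binds viral RNA lacking cap methylation, rose 17-fold to 10.6 ± 1 FPKM, and OAS1 rose 3-fold to 18.2 ± 0.61. MX1 went from 0.146 ± 0.041 to 3.22 ± 0.0073 FPKM and the chemokine CXCL10 from 0.239 ± 0.073 to 2.49 ± 0.18, both past the threshold. CCL5 was listed at 0 in all 4 libraries without irradiation and at 0.3223 and 0.3302 FPKM in the IR libraries. Transcripts of the interferons themselves stayed low: IFNB1 was at 0.0486 ± 0.041 FPKM in IR and 0.0105 ± 0.015 in DMSO, with adjusted p = 0.492. IFNL1 was listed at 0 in DMSO and at 0.1162 and 0.2534 FPKM in IR, a call with adjusted p = 0.0343 that was lost without IR B (adjusted p = 0.15), without either DMSO library (0.103), without either AZD6738 library (0.0568) and with the library letter as a block (0.0559). The list of interferons and their receptors had 5 members higher and 1 lower of 10, the same counts when adjusted over the list alone, with a median of 0.18 and camera adjusted p = 0.0265. Its adjusted p = 0.169 with an estimated correlation, 0.0597 under quantile normalization and 0.123 with a mean of at least 5 FPKM.

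Genes of the list of cytosolic nucleic acid sensing, not all of them sensors, moved in both directions with irradiation. Of 12, 6 were higher and 4 lower, against 6 and 5 when adjusted over the list alone. IFIH1, the RNA sensor MDA5, rose 1.64-fold to 6.7 ± 0.33 FPKM, and TMEM173, the adaptor STING, rose 1.55-fold to 15.9 ± 0.068. MB21D1, the DNA sensor cGAS, fell by 0.24 on the log2 scale, a call that ended without DMSO A (adjusted p = 0.0527), without IR A (0.058) and under quantile normalization (0.0675). RNASEH2A and RNASEH2B, subunits of the enzyme that removes ribonucleotides from DNA, fell to 6.43 ± 0.31 and 5.54 ± 0.26 FPKM. The list as a whole had camera adjusted p = 0.294. RIGI, MAVS, AIM2, IFI16, TBK1, TREX1, RNASEH2C, ENPP1 and ZNFX1 of this list had no matching symbol in the table, so they have no result under their names in any comparison. Whether some of them are among the loci without a symbol was not examined. Of 13 antigen presentation genes, 6 rose and none fell, with the same counts when adjusted over the list alone, a median of 0.8 and camera adjusted p = 0.0012. With an estimated correlation its adjusted p = 0.122. HLA-F rose 2.75-fold to 4.42 ± 0.04 FPKM and HLA-C 1.78-fold to 30.9 ± 0.59. HLA-C, like HLA-B, had several entries in the table, of which the one with the highest mean was used, so its level is uncertain.

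Targets of p53 were mostly higher after irradiation, with 18 of 25 rising and FUCA1 alone falling, in equal numbers when adjusted over the list alone. The median was 0.5, with camera adjusted p = 4.01e-08 and with adjusted p = 0.0596 with an estimated correlation. PLK2 rose 3.86-fold to 81.4 ± 1.1 FPKM, TIGAR, a regulator of glycolysis, rose 2.88-fold to 10.2 ± 0.12, and MDM2, a ubiquitin ligase, rose 2.35-fold to 99.9 ± 0.56. All 32 genes of G2/M and mitosis fell, with a median of -0.91, also when adjusted over the list alone, with camera adjusted p = 1.18e-09 and with adjusted p = 0.169 with an estimated correlation. LMNB1, the nuclear lamina protein lamin B1, fell 2.95-fold to 2.91 ± 0.026 FPKM, CCNB2 2.84-fold to 5.57 ± 0.14, CCNB1 2.16-fold to 11.6 ± 0.088 and MKI67, a marker of proliferating cells, 2.15-fold to 3.2 ± 0.15. Of 31 genes of DNA replication and G1/S, 21 fell and 3 rose, or 23 and 4 when adjusted over the list alone, with a median of -0.38, camera adjusted p = 0.00169 and adjusted p = 0.169 with an estimated correlation. The licensing factor CDT1 fell 3.71-fold to 2.02 ± 0.24 FPKM and ORC1 fell 3.96-fold to 1.28 ± 0.079. Replication-dependent histone genes fell in 50 of 55 cases and rose in 1, or 51 and 1 when adjusted over the list alone, with a median of -1.12, camera adjusted p = 5.15e-11 and adjusted p = 0.169 with an estimated correlation. HIST2H2AB fell 3.82-fold to 11.6 ± 0.22 FPKM and HIST1H3I 4.33-fold to 5.47 ± 0.45, where single members are uncertain because histone genes are near-identical. In the list of the ATR pathway and DNA damage response, 14 of 19 fell and 2 rose, with the same counts when adjusted over the list alone, a median of -0.27, camera adjusted p = 0.0249 and adjusted p = 0.169 with an estimated correlation. That list did not pass without IR A (adjusted p = 0.0748) or with a mean of at least 5 FPKM (0.437). CHEK1, the effector kinase of ATR, fell to 2.17 ± 0.14 FPKM, and ATR itself (chromosome 3, 142449235 to 142578826) rose from 6.06 ± 0.24 to 8.03 ± 0.13.

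Most inflammatory and epithelial genes on the lists also rose after irradiation. Of 17 NF-kB targets and inflammatory secreted factors, 15 rose and 1 fell, also when adjusted over the list alone, with a median of 1.07, camera adjusted p = 1.97e-08 and adjusted p = 0.169 with an estimated correlation. The neutrophil chemokine CXCL1 rose 19-fold to 145 ± 5.3 FPKM, the cytokine LIF 6.98-fold to 24.5 ± 2, and the urokinase gene PLAU 4.06-fold to 48.3 ± 5.4. Squamous differentiation genes rose in 12 of 14 cases and fell in 1, with the same counts when adjusted over the list alone, a median of 2.33, camera adjusted p = 9.98e-08 and adjusted p = 0.169 with an estimated correlation. Beside S100A7, LCN2 rose 16.2-fold to 31.7 ± 3.4 FPKM, IVL, the cornified envelope protein involucrin, 12.7-fold to 14.6 ± 1.3, and S100A8 7.6-fold to 1329 ± 130. In the list of basal and luminal epithelium, 11 of 13 rose and 2 fell, also when adjusted over the list alone, with a median of 0.57, camera adjusted p = 0.00018 and adjusted p = 0.169 with an estimated correlation. The luminal keratin KRT8 rose 3.02-fold to 135 ± 0.06 FPKM, and TP63, the basal transcription factor, was 1 of the 2 that fell, to 7.65 ± 0.47. Outside these lists GJA5, the gap junction protein connexin 40, rose 29.6-fold to 30.8 ± 0.31 FPKM, CPA4 19.9-fold to 26.9 ± 0.4, IGFL1 17.1-fold to 72.3 ± 2.7 and PDZK1IP1 15.5-fold to 121 ± 9.6.

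Mesenchymal and matrix genes, listed as markers of other cell types but measured here in a single cell line, split after irradiation. Of 10, 6 were higher and 4 lower, also when adjusted over the list alone. Their median was 0.29 and their mean -0.01, with camera adjusted p = 0.341 in the upward direction. TAGLN rose 6.38-fold to 8.6 ± 0.19 FPKM, whereas COL4A2 fell 4.3-fold to 1.84 ± 0.066 and VIM 2.79-fold to 56.9 ± 1.2. Among markers of blood and immune cells only CSF1R and CD14 could be tested, too few for a list test. CSF1R rose from 0.737 ± 0.015 to 4.71 ± 0.17 FPKM and CD14 fell from 15.7 ± 0.21 to 13.1 ± 0.15. Cholesterol synthesis genes rose in 7 of 14 cases and fell in 1, with the same counts when adjusted over the list alone, a median of 0.29, camera adjusted p = 0.00971 and adjusted p = 0.25 with an estimated correlation. FDPS, farnesyl diphosphate synthase, rose 2.16-fold to 393 ± 6.5 FPKM.

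Beside ASNS, the translation repressor gene EIF4EBP1 fell 5.57-fold to 37.7 ± 4.2 FPKM after irradiation, TRIB3 4.66-fold to 28.4 ± 0.7, the serine synthesis gene PSAT1 4.07-fold to 17.5 ± 1.9, PCK2 5.94-fold to 3.43 ± 0.53 and CBS, of the transsulfuration pathway, from 5.63 ± 1.6 to 0.229 ± 0.1. The growth factor gene FIGF fell 6.97-fold to 2.16 ± 0.027 FPKM and MACROD1 7.7-fold to 1.36 ± 0.12. The list of the integrated stress response and unfolded protein response had 10 of 17 lower and 1 higher, also when adjusted over the list alone, with a median of -0.51, but did not pass as a whole, with camera adjusted p = 0.0643, or 0.412 with an estimated correlation. At the preset correlation it did pass without DMSO B (adjusted p = 0.0236), without IR A (0.0392), with libraries centred on their median (0.0369), without the filter on low values (0.0386) and with the library letter as a block (0.0294). Ribosomal protein genes fell in 42 of 58 cases and rose in 1, or 43 and 1 when adjusted over the list alone, with a median of -0.28, between -0.23 and -0.19 under the other scalings of the libraries. Their camera adjusted p = 3.07e-05, and adjusted p = 0.196 with an estimated correlation. RPL3 (chromosome 22, 39312882 to 39320389) fell 1.58-fold, from 941 ± 6.9 to 596 ± 18 FPKM.

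In all, 7912 of 12809 tested loci passed the threshold between IR and DMSO (limma, adjusted p under 0.05), 3040 higher and 4872 lower, of which 550 rose and 363 fell by at least 1 on the log2 scale. The median over all tested loci was -0.1 log2, and no other scaling moved such a median by more than 0.1 in any comparison. Fry, which asks whether the genes of a set move on balance one way and does not compare them with other genes, gave adjusted p = 2.6e-05 for the interferon-stimulated genes.

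AZD6738 was compared with DMSO to give the effect of the inhibitor without radiation. Only 19 loci passed the threshold, a count that ranged from 16 to 41 with 1 library left out, and none was on the lists of interferon-stimulated genes, p53 targets and cell cycle genes. SLC38A2, an amino acid transporter, rose 1.59-fold, from 58.4 ± 2.2 to 92.8 ± 2.1 FPKM, with limma adjusted p = 0.0081, or 0.0717 when only these groups were fitted. TRAPPC2, of a vesicle tethering complex, rose 3.79-fold, from 1.5 ± 0.0014 to 5.68 ± 0.43 FPKM, and MCFD2, of cargo export from the endoplasmic reticulum, was lower at 7.62 ± 0.62 than in DMSO at 34.5 ± 0.79, with a log2 fold change of -2.05 and adjusted p = 0.000282. LRRC37BP1 fell from 13.2 ± 0.96 to 2.83 ± 0.27 FPKM and SHISA5 from 28.4 ± 0.93 to 11 ± 0.18, and the SHISA5 call ended without any single DMSO or AZD6738 library, with adjusted p from 0.0577 to 0.0784. IGFL1 at 6.93 ± 0.07, RFWD3 at 5.82 ± 0.06 and IRX5 at 7.51 ± 0.3 FPKM also passed, against 4.23 ± 0.036, 4.06 ± 0.14 and 10.6 ± 0.43 in DMSO, and each lost its call without any single library of DMSO, AZD6738 or IR. Their adjusted p then ranged from 0.0504 to 0.0804 for IGFL1, from 0.0869 to 0.142 for RFWD3 and from 0.0804 to 0.139 for IRX5, and the calls of RFWD3 and IRX5 also ended without either AZD6738+IR library, with adjusted p from 0.0559 to 0.057, and with the library letter as a block (0.1 and 0.0562). TAPBP was listed at 0 in both DMSO libraries and at 2.221 and 2.307 FPKM in AZD6738, but the symbol had several entries, of which the one with the highest mean was used, and its level is uncertain.

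No interferon-stimulated gene passed the genome-wide threshold with the inhibitor alone, against 8 of 29 higher when adjusted over the list alone, with a median of 0.09, camera adjusted p = 2.3e-06 and adjusted p = 0.235 with an estimated correlation. ISG15 was at 5.73 ± 0.14 against 2.49 ± 0.7 FPKM, with adjusted p = 0.121, and IFIT1 at 1.2 ± 0.0048 against 0.625 ± 0.12, with adjusted p = 0.124. Of 25 p53 targets none passed genome-wide and 10 were higher when adjusted over the list alone, with a median of 0.11, camera adjusted p = 2.37e-08 and adjusted p = 0.0534 with an estimated correlation. CDKN1A was at 79.2 ± 0.35 against 54.1 ± 1.5 FPKM with adjusted p = 0.0964, and passed on leaving out either AZD6738+IR library, with adjusted p = 0.0269 and 0.0267. Medians were -0.13 for DNA replication and G1/S and -0.15 for G2/M and mitosis, with none genome-wide and 7 of 31 and 2 of 32 lower when adjusted over the list alone. Camera adjusted p = 2.37e-08 and 3.98e-08 for these lists, and adjusted p = 0.178 and 0.235 with an estimated correlation. Among NF-kB targets none passed genome-wide and 7 of 17 were higher when adjusted over the list alone, with a median of 0.24, camera adjusted p = 2.37e-08 and adjusted p = 0.214 with an estimated correlation. The integrated stress response list had a median of 0.26 with none passing either way, camera adjusted p = 6.04e-06 and adjusted p = 0.235 with an estimated correlation. Squamous differentiation genes had a median of 0.16 and camera adjusted p = 0.0124, which was lost with an estimated correlation (0.425), without DMSO A (0.18) and without AZD6738 B (0.307), with none genome-wide and 1 of 14 lower when adjusted over the list alone. The basal and luminal list had a median of 0.08 and camera adjusted p = 0.0224, lost likewise with an estimated correlation (0.384), without DMSO A (0.056) and without AZD6738 B (0.0851), with none genome-wide and 3 of 13 higher when adjusted over the list alone. Histone genes had a median of 0.08 with camera adjusted p = 2.73e-07, and adjusted p = 0.294 with an estimated correlation, with none genome-wide and 1 of 55 higher when adjusted over the list alone. Ribosomal protein genes had a median of -0.03 and camera adjusted p = 0.0344, and adjusted p = 0.425 with an estimated correlation, with none passing either way. This call ended without DMSO B (adjusted p = 0.809), without AZD6738 A (0.304) and under quantile normalization (0.126). Fry gave adjusted p = 0.0377 for interferon-stimulated genes, 0.00643 for p53 targets, 0.0142 for DNA replication and G1/S and 0.0158 for NF-kB targets. It gave 0.0521 for G2/M and mitosis and for the integrated stress response, and 0.0894 for histones and the basal and luminal list. For squamous differentiation and ribosomal protein genes it gave 0.297 and 0.266. ATR itself was at 5.98 ± 0.17 against 6.06 ± 0.24 FPKM with limma adjusted p = 0.918.

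The inhibitor alone passed the threshold at 19 of 12809 loci, 12 higher and 7 lower, while 1758 had an unadjusted limma p under 0.05, against 640 by chance. Leaving out 1 library moved the count by over 1.5 times in 5 cases: to 34 without DMSO B, 41 without AZD6738 A, 36 without AZD6738 B, and 31 without either AZD6738+IR library. The split into higher and lower loci turned with the library left out, from 19 and 3 without DMSO A to 11 and 25 without AZD6738 B, and without a DMSO or AZD6738 library only 8 or 9 of the 19 loci were called again.

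**Figure D2:**
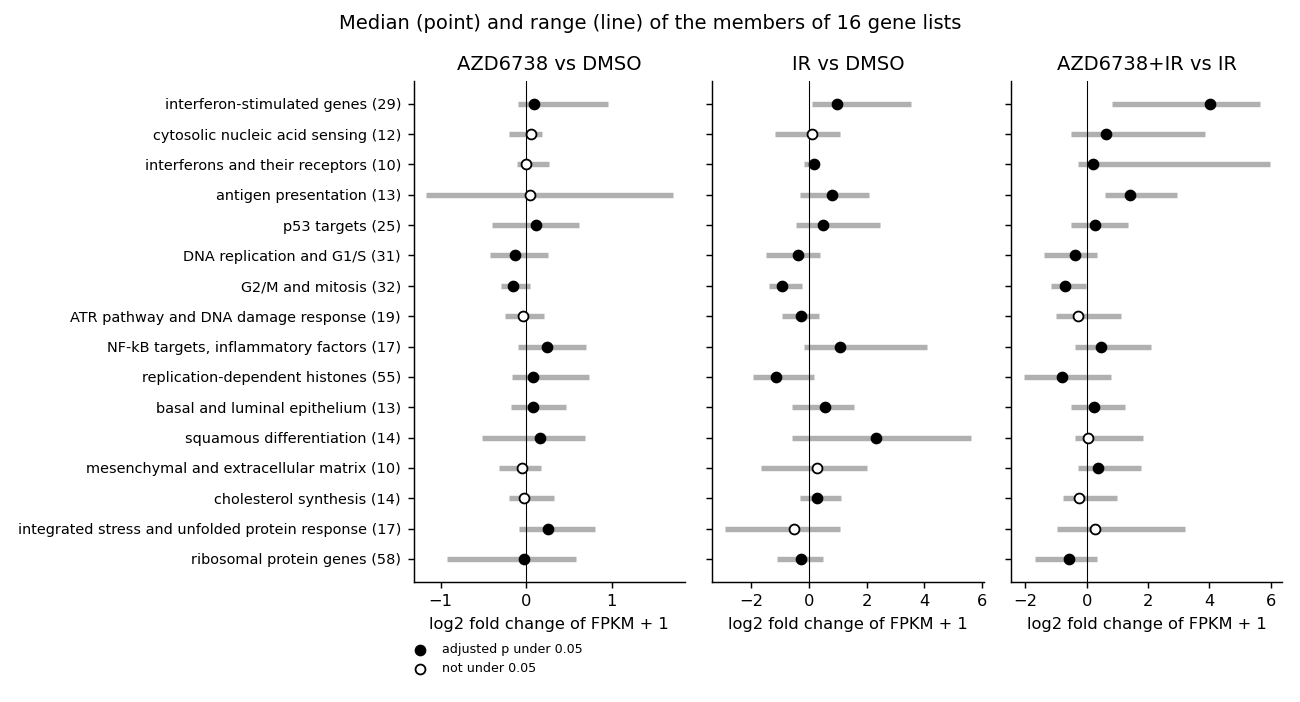
Median (point) and range (line) of the log2 fold change of FPKM + 1 over the tested members of the 16 gene lists, with the number of members after each name, in 3 comparisons. A filled point marks a camera adjusted p under 0.05 with the preset correlation. Interferon-stimulated genes have medians of 0.09, 0.97 and 4.01 from left to right.

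AZD6738+IR was compared with IR to ask what the inhibitor adds in irradiated cells. IFNB1 and genes of type III interferons rose, all interferon-stimulated genes tested and most antigen presentation genes rose above their level with radiation alone, and most histone, cell cycle and ribosomal protein genes fell below it. No list of this comparison passed camera with an estimated correlation, where the lowest adjusted p = 0.0518. ISG15 rose 51.3-fold, from 32.2 ± 5.1 to 1650.1 ± 65 FPKM, and IFIT1 53.6-fold, from 10.6 ± 1 to 569.7 ± 6.6. IFNB1 (chromosome 9, 21077105 to 21077963), the gene of interferon beta, rose from 0.0486 ± 0.041 to 10.2 ± 0.63 FPKM. IFNL1 (chromosome 19, 39296325 to 39298673), of a type III interferon, rose from 0.185 ± 0.097 to 73.7 ± 5.5 FPKM, with a log2 fold change of 5.98 ± 0.08 (SE) and limma adjusted p = 6.67e-07. RPL3, a protein of the large ribosomal subunit, fell 2.69-fold, from 596 ± 18 to 221 ± 6.4 FPKM.

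All 29 interferon-stimulated genes rose when the inhibitor was added to radiation, also when adjusted over the list alone, by a median of 4.01, with camera adjusted p = 6.91e-28 and adjusted p = 0.0518 with an estimated correlation. OASL rose 58.9-fold to 329 ± 11 FPKM, IFIT3 53.7-fold to 655 ± 16, RSAD2, the antiviral enzyme viperin, from 0.892 ± 0.31 to 80.6 ± 4, and IFI6 38.5-fold to 1609 ± 116. MX1 reached 121 ± 1.6, OAS1 229 ± 2.7 and CXCL10 55.2 ± 1.1 FPKM. CCL5 was at 26.79 and 22.5 FPKM in the AZD6738+IR libraries. Of the 10 interferons and receptors tested, 5 rose and IFNAR1 fell, also when adjusted over the list alone. IFNL3 and IFNL2 (chromosome 19, starting at 39243553 and 39268514) rose to 40.9 ± 0.73 and 34.8 ± 2.1 FPKM, and are uncertain as single genes because their sequences are near-identical. That list had a median of 0.2 and a mean of 1.93, with camera adjusted p = 0.00235 and adjusted p = 0.0939 with an estimated correlation.

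Among genes of nucleic acid sensing, 8 of 12 rose and 2 fell when the inhibitor was added, or 9 and 2 when adjusted over the list alone, with a median of 0.62, camera adjusted p = 5.67e-05 and adjusted p = 0.0792 with an estimated correlation. IFIH1 rose 16.7-fold to 112 ± 1.2 FPKM, SAMHD1, a nucleotide hydrolase, 12.2-fold to 68.9 ± 0.46, TLR3, the endosomal receptor of double-stranded RNA, 6.5-fold to 36.4 ± 0.12, TRIM25 3.18-fold to 43.6 ± 2.6, and TMEM173 2.33-fold to 37.1 ± 2.3. MB21D1 was at 7.7 ± 0.45 against 6.88 ± 0.24 FPKM with adjusted p = 0.0731, and passed without AZD6738+IR A (0.0435) and with equal totals outside the 4 most abundant loci (0.0376). Antigen presentation genes rose in 9 of 13 cases and none fell, with 11 higher when adjusted over the list alone, a median of 1.4, camera adjusted p = 3.12e-07 and adjusted p = 0.0518 with an estimated correlation. HLA-B rose 8.68-fold to 56.3 ± 13 FPKM, HLA-C 5.67-fold to 175 ± 27, and CD274, the immune checkpoint ligand PD-L1, 16.5-fold to 10.5 ± 0.46.

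**Figure D3:**
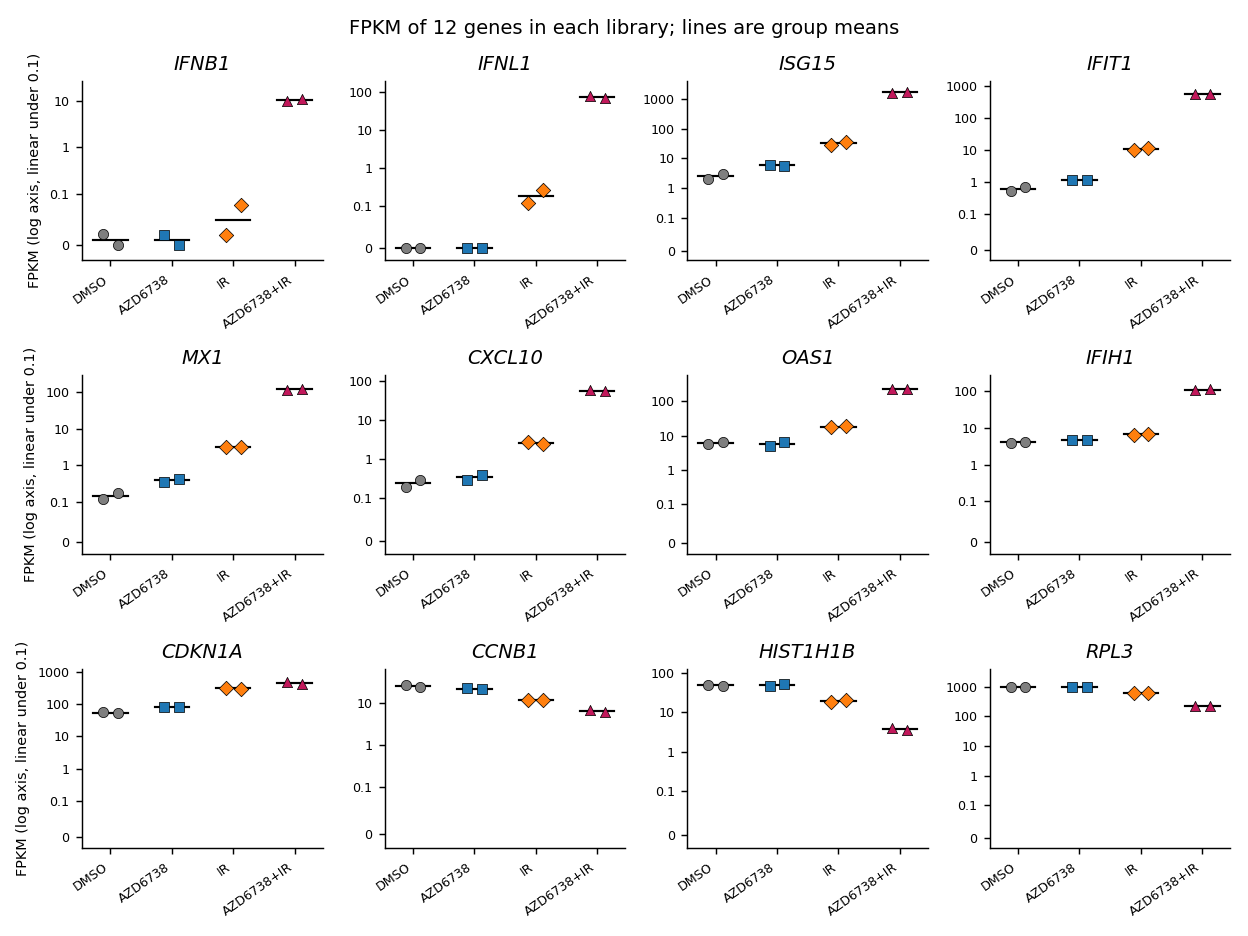
FPKM of 12 genes in each library (points) with group means (lines), on a log axis that is linear under 0.1. IFNB1 and IFNL1 reach means of 10.2 and 73.7 FPKM with both treatments, and RPL3 has means of 941, 932, 596 and 221 FPKM from left to right.

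Most proliferation and histone genes fell below their level in IR. Of 32 genes of G2/M and mitosis, 30 fell and none rose, also when adjusted over the list alone, with a median of -0.71, camera adjusted p = 1.14e-09 and adjusted p = 0.135 with an estimated correlation. TOP2A fell 2.61-fold to 3.71 ± 0.12 FPKM, CENPF 2.68-fold to 3.01 ± 0.24, MKI67 2.34-fold to 1.37 ± 0.0089 and LMNB1 2.3-fold to 1.26 ± 0.07. DNA replication genes fell in 23 of 31 cases and rose in 1, or 24 and 1 when adjusted over the list alone, with a median of -0.39, camera adjusted p = 5.67e-05 and adjusted p = 0.135 with an estimated correlation. RRM2, a subunit of ribonucleotide reductase, fell 3.13-fold to 3.17 ± 0.15 FPKM. Histone genes fell in 42 of 55 cases and rose in 3, or 44 and 4 when adjusted over the list alone, with a median of -0.8, camera adjusted p = 1.33e-07 and adjusted p = 0.207 with an estimated correlation. HIST1H1B fell 5.02-fold to 3.8 ± 0.32 FPKM and HIST1H3G 4.22-fold to 4.34 ± 0.84. In the list of the ATR pathway and DNA damage response 12 of 19 fell and 3 rose, also when adjusted over the list alone, and its camera adjusted p = 0.0878, or 0.049 without IR A and 0.0108 with a mean of at least 5 FPKM. ATR fell from 8.03 ± 0.13 to 5.62 ± 0.14 FPKM, RBBP8, the resection factor CtIP, 2.05-fold to 13.7 ± 0.37, and PRKDC, the catalytic subunit of DNA-dependent protein kinase, 1.92-fold to 16.7 ± 0.29, while RAD9A rose from 0.999 ± 0.041 to 3.32 ± 0.39.

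Ribosomal protein genes fell in 51 of 58 cases and rose in 1 on adding the inhibitor, or 52 and 1 when adjusted over the list alone. The median was -0.59, and between -0.57 and -0.38 under the other scalings, with camera adjusted p = 2.88e-13 and adjusted p = 0.0939 with an estimated correlation. The share of the total taken by the 4 most abundant loci, given above, was also highest in AZD6738+IR. RPL10A fell 2.12-fold to 339 ± 2.8 FPKM, RPS3A 2.24-fold to 44.7 ± 0.1 and RPL5 2.12-fold to 339.6 ± 20 FPKM. MALAT1, a nuclear long non-coding RNA, fell 3.33-fold, from 613 ± 91 to 184 ± 8.8 FPKM, and LRRC37BP1 5.86-fold to 1.45 ± 0.1. PRPF8 at 0.416 ± 0.16 against 10.6 ± 4.2 FPKM and SSR3 at 7.82 ± 0.58 against 28.5 ± 0.034 passed with all libraries, but neither did so without any single IR or AZD6738+IR library, with adjusted p from 0.0644 to 0.116 for PRPF8 and from 0.092 to 0.113 for SSR3. The SSR3 call also ended without AZD6738 A (adjusted p = 0.0522) or B (0.0519) and with the library letter as a block (0.0502).

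Targets of p53 rose in 14 of 25 cases and fell in 5, also when adjusted over the list alone, with a median of 0.27, camera adjusted p = 0.00103 and adjusted p = 0.0858 with an estimated correlation. GDF15, a stress cytokine, rose 2.56-fold to 109 ± 17 FPKM, GADD45A 2.1-fold to 60.2 ± 2.8, BBC3, the apoptosis gene PUMA, 2.19-fold to 6.85 ± 0.053, CDKN1A 1.53-fold to 461 ± 49 and MDM2 1.28-fold to 128 ± 2.5. NF-kB targets and secreted factors rose in 12 of 17 cases and fell in 1, also when adjusted over the list alone, with a median of 0.47, camera adjusted p = 9.94e-06 and adjusted p = 0.148 with an estimated correlation. IL6 rose from 0.439 ± 0.087 to 5.16 ± 0.076 FPKM, PLAUR, the urokinase receptor, 3.23-fold to 97.3 ± 12, and TNFAIP3 2.53-fold to 20.5 ± 0.87. The basal and luminal list had 8 of 13 higher and 2 lower, also when adjusted over the list alone, with a median of 0.24, camera adjusted p = 0.0067 and adjusted p = 0.237 with an estimated correlation. KRT8 rose 2.39-fold to 323 ± 18 FPKM and KRT17 1.89-fold to 3236 ± 175, whereas TP63 fell to 4.98 ± 0.41. Mesenchymal genes rose in 7 of 10 cases and fell in 3, also when adjusted over the list alone, with a median of 0.36, camera adjusted p = 0.0111 and adjusted p = 0.207 with an estimated correlation, but camera adjusted p = 0.136 with a mean of at least 5 FPKM. FN1, fibronectin, rose 4.3-fold to 11.8 ± 0.22 FPKM. Squamous differentiation genes had 6 of 14 higher and 3 lower, also when adjusted over the list alone, with camera adjusted p = 0.136, or 0.0346 without the filter on low values and 0.0444 with a mean of at least 5 FPKM, and LCN2 rose 3.66-fold to 116 ± 8.7 FPKM. Cholesterol synthesis genes had 2 of 14 higher and 8 lower, also when adjusted over the list alone, with camera adjusted p = 0.136, and FDPS fell 1.57-fold to 251 ± 0.27 FPKM. The integrated stress response list had 7 of 17 higher and 4 lower, or 7 and 5 when adjusted over the list alone, with camera adjusted p = 0.0727, or 0.0316 without AZD6738+IR A and 0.0212 with a mean of at least 5 FPKM. ATF3, a stress-induced transcription factor, rose 12.2-fold to 34.2 ± 1.8 FPKM and PPP1R15A 2.76-fold to 40 ± 1.6, whereas PSAT1 fell 2.08-fold to 8.41 ± 0.18.

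Between AZD6738+IR and IR, 6546 of 12809 loci passed the threshold, 2506 higher and 4040 lower, with 342 and 112 changed by at least 1 on the log2 scale. Without AZD6738+IR B, whose total stood apart, 5990 loci passed.

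The interaction asked for each locus whether the effect of radiation differed with and without the inhibitor. It was positive for every interferon-stimulated gene tested and negative for most histone, mitotic and ribosomal protein genes, but no list passed camera with an estimated correlation, where the lowest adjusted p = 0.0686. Antigen presentation had that value at an estimated correlation of -0.06, below the preset 0.01, so correlation between its members does not account for its loss. IFIT3 had an interaction of 5.34 ± 0.17 (SE) on the log2 scale, OASL 5.27 ± 0.07 and RSAD2 5.32 ± 0.16. IFNL1 at 5.98 ± 0.11, IFNL3 at 5.21 ± 0.06 and IFNB1 at 3.42 ± 0.09 showed the same direction. At the other end were HIST1H1B at -2.06 ± 0.12, MALAT1 at -2.01 ± 0.2, HIST1H3G at -2 ± 0.17, RPL22L1 at -2.27 ± 0.44, and ODC1, the rate-limiting enzyme of polyamine synthesis, at -1.79 ± 0.08. ODC1 had means of 90.2, 105, 40.5 and 13 FPKM in DMSO, AZD6738, IR and AZD6738+IR.

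All 29 interferon-stimulated genes passed with a positive interaction, also when adjusted over the list alone, with a median of 3.9, camera adjusted p = 2.8e-32 and adjusted p = 0.0686 with an estimated correlation. Antigen presentation genes were positive in 9 of 13 cases and negative in 1, also when adjusted over the list alone, with a median of 1.81, camera adjusted p = 1.75e-05 and adjusted p = 0.0686 with an estimated correlation. Of 12 genes of nucleic acid sensing, 8 were positive and 2 negative, also when adjusted over the list alone, with a median of 0.69, camera adjusted p = 6.05e-05 and adjusted p = 0.0774 with an estimated correlation. Among them were IFIH1 at 3.7 ± 0.07 and TMEM173 at 1.19 ± 0.07, while MB21D1 was at 0 ± 0.08 with adjusted p = 0.969. The p53 targets had 5 of 25 positive and 5 negative, also when adjusted over the list alone, with camera adjusted p = 0.0693, which passed without DMSO B (0.0399), under quantile normalization (0.0311) and with the library letter as a block (0.0495). CDKN1A was at 0.06 ± 0.1 with adjusted p = 0.674 and MDM2 at 0.08 ± 0.04 with adjusted p = 0.208. Mitotic genes were negative in 24 of 32 cases, or 27 when adjusted over the list alone, with a median of -0.56, camera adjusted p = 2.08e-08 and adjusted p = 0.191 with an estimated correlation. Histone genes were negative in 40 of 55 cases and positive in 2, or 43 and 2 when adjusted over the list alone, with a median of -0.89, camera adjusted p = 2.66e-10 and adjusted p = 0.191 with an estimated correlation. Ribosomal protein genes were negative in 46 of 58 cases, or 48 with 1 positive when adjusted over the list alone, with a median of -0.57, camera adjusted p = 4.75e-13 and adjusted p = 0.116 with an estimated correlation. The squamous list had 1 of 14 positive, LCN2, and 1 negative, IVL, also when adjusted over the list alone, with camera adjusted p = 0.403. The IVL call ended without DMSO A (adjusted p = 0.0669), DMSO B (0.0694), AZD6738 B (0.0733), IR A (0.0725) or AZD6738+IR B (0.0544).

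The interaction passed at 4542 of 12809 loci, 1673 positive and 2869 negative. Across loci, the effect of radiation without the inhibitor and its effect with the inhibitor, which share no library, had Pearson's r = 0.74 and Spearman's rho = 0.78, where loci are not independent replicates. Of loci higher in each, 2380 were shared against 824.5 for independent lists, and of loci lower in each, 4175 were shared against 2204.6, while 337 of the 6892 loci called in both went in opposite directions. The effect of the inhibitor without and with radiation had r = 0.1 and rho = 0.17 over the same loci, with 7 shared higher and 4 shared lower against 2.3 and 2.2, and 5 of the 16 called in both in opposite directions.

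**Figure D4:**
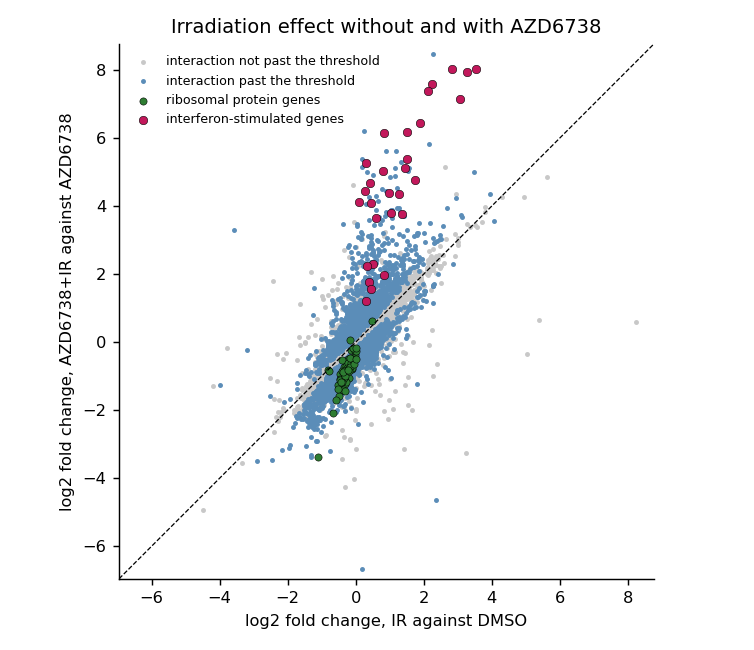
Log2 fold change of FPKM + 1 of each tested locus for IR against DMSO (horizontal) and AZD6738+IR against AZD6738 (vertical), with equal effects on the dashed line and colours for the interaction test and 2 gene lists. All 29 interferon-stimulated genes lie above the line, with medians of 0.97 and 4.68.

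AZD6738+IR was also compared with AZD6738 and with DMSO, which gives the effect of radiation in inhibited cells and of the whole treatment. Against DMSO, ISG15 was 663-fold higher, IFI6 592-fold, IFIT1 911-fold, IFIT3 364-fold and IFI27 411-fold, and CDKN1A was 8.52-fold higher. HIST1H1B fell 12.8-fold, ASNS 10.6-fold, EIF4EBP1 10.6-fold, PSAT1 8.49-fold and HIST1H3G 10.9-fold. All 29 interferon-stimulated genes rose in both comparisons, also when adjusted over the list alone, with a median of 4.68 in each, camera adjusted p = 8.56e-21 and 1.31e-20, and adjusted p = 0.0585 and 0.0594 with an estimated correlation. All 32 mitotic genes fell in both, also when adjusted over the list alone, by medians of -1.46 against AZD6738 and -1.63 against DMSO, with camera adjusted p = 1.99e-09 and 1.35e-09, and with adjusted p = 0.143 and 0.139 with an estimated correlation. Ribosomal protein genes fell in 53 and 56 of 58 cases, with 1 rising in each and the same counts when adjusted over the list alone, by medians of -0.84 and -0.86. These had camera adjusted p = 1.99e-09 and 1.15e-09, and adjusted p = 0.143 and 0.134 with an estimated correlation. Against AZD6738, 9270 loci passed, 3474 higher and 5796 lower, and against DMSO 9311 did, 3475 higher and 5836 lower. The medians over all tested loci were -0.15 and -0.16.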

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

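The scaling and single-library tests of the interferon-stimulated genes, and the scaling and oligopyrimidine-tract tests of the ribosomal protein genes, with camera on the latter, were chosen after their results had been seen. Single genes in this part drew attention because their limma interaction passed the threshold, that is, the effect of radiation with AZD6738 differed from that without it. The limma interaction passed for 4542 loci. Lists drew attention because camera at the preset correlation passed for the interaction. Median interactions on the log2 scale were 3.9 for interferon-stimulated genes, 0.69 for cytosolic nucleic acid sensing, 0.13 for interferons and their receptors (mean 1.88), 1.81 for antigen presentation, 0.42 for NF-kB targets and 0.6 for mesenchymal genes. They were -0.32 for DNA replication and G1/S, -0.56 for G2/M and mitosis, -0.89 for histones and -0.57 for ribosomal protein genes. Camera with the preset correlation passed for each of these lists, and none passed with an estimated correlation, where the lowest adjusted p = 0.0686. Single genes with a positive interaction were IFNL1 at 5.98, IFIT3 at 5.34, RSAD2 at 5.32, OASL at 5.27, IFNL3 at 5.21, IFIT1 at 5.18, ISG15 at 4.68, MX1 at 4.57, CCL5 at 4.27, CXCL10 at 3.9, IFIH1 at 3.7, OAS1 at 3.67, IFNB1 at 3.42 and TMEM173 at 1.19. Negative ones were RPL22L1 at -2.27, HIST1H1B at -2.06, MALAT1 at -2.01, HIST1H3G at -2, ODC1 at -1.79, TRAPPC2 at -1.76, MKI67 at -0.71, LMNB1 at -0.58, CCNB1 at -0.54 and ATR at -0.43.

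Interferon-stimulated genes rose far more with radiation and AZD6738 together than with radiation alone. The size of this difference depends on the added 1 for members with low levels in DMSO, such as MX1 and CXCL10. Scaling of the libraries is argued against by a median interaction of at least 3.92 under the other scalings, and a single library by one of at least 3.84 without each library in turn. Across the 29 members, the effects of radiation without and with the inhibitor, which share no library, had Pearson's r = 0.81 and Spearman's rho = 0.74, with permutation p = 1e-05 for r, the smallest that 100000 permutations can give, where genes are not independent replicates. The same effects had r = 0.74 over all 12809 loci, and genes that interferon induces would correlate under any interferon signal, so an enlarged response to radiation and a further signal started by the inhibitor cannot be told apart by this value. Whether more nucleic acid reached the sensors, or the same signal was relayed further, was not tested.

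Ribosomal protein genes fell with both treatments by a median of -0.59 against IR, with camera adjusted p = 2.88e-13 and adjusted p = 0.0939 with an estimated correlation. Scaling did not remove this, with a median of -0.38 or lower under each other scaling. Random lists drawn from the nearest loci in length and abundance, which take genes as independent, had a median of only -0.18, with 0 of 10000 at or below the list. How near these loci came was not recorded, so length and abundance are not excluded. Other mRNAs known to carry a terminal oligopyrimidine tract at their 5-prime end, which are translated under growth control, had a median of -0.71. All 21 were lower, among them the ribosomal protein gene FAU, with camera adjusted p = 9.71e-10 and adjusted p = 0.099 with an estimated correlation. A shared loss of these mRNAs may thus lie behind the pattern, as a hypothesis found and tested on the same data. RNA quality was not measured in a way that would exclude a faster decay of such RNAs during preparation, so that stays open.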

How the results depend on the processing

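Keeping every entry of a repeated symbol, scaling to equal totals outside the 4 most abundant loci, named loci alone and the library letter as a block were chosen after seeing the data. Of 7642 results for single genes under the alternatives, 7519 kept direction and side of the threshold, 116 lost the call, 6 gained it and 1 turned: CD14 in AZD6738+IR against DMSO went to 0 under quantile normalization (limma adjusted p = 0.991), and the cause was not tested. Of 1904 results for lists, 1790 stayed on their side, 87 lost the call and 27 gained it. The excess of lower over higher loci shrank under other scalings without turning: from 38.4% higher to 46.9% with median centring for IR against DMSO, and with equal totals outside the most abundant loci from 38.3% to 46.2% for AZD6738+IR against IR and from 36.8% to 45.7% for the interaction. Requiring a log2 fold change of at least 1 left 6 loci for AZD6738 against DMSO, 913 for IR against DMSO, 454, 2003 and 2175 for AZD6738+IR against IR, AZD6738 and DMSO, and 438 for the interaction, by construction. A mean of at least 5 FPKM, with fewer loci tested, left 6, 4686, 4124, 5459 and 5470 for the comparisons other than the interaction. With an estimated correlation the interferon-stimulated genes no longer passed, at the same medians of 0.09 (p = 0.235), 0.97 (p = 0.122), 4.01 (p = 0.0518), 4.68 (p = 0.0585), 4.68 (p = 0.0594) and, for the interaction, 3.9 (p = 0.0686). Fry, which does not compare a list with other loci, gave this list adjusted p = 0.0377, 2.6e-05, 2.06e-07, 8.18e-08, 7.25e-08 and 9.64e-07 in the same order. For ribosomal protein genes fry gave adjusted p = 0.266, 0.000205, 1.58e-05, 3.19e-06, 2.12e-06 and 7.37e-05. Leaving out 1 library in turn gave 16 to 41 loci for AZD6738 against DMSO, with 34 (25 higher) without DMSO B, 41 (20 higher) without AZD6738 A, 36 (11 higher) without AZD6738 B and 31 (19 higher) without either AZD6738+IR library, against 19 (12 higher) with all libraries. Fitting only AZD6738 and DMSO gave 15 loci, 6 of them among the 19. The ranges were 6528 to 8215 for IR against DMSO, 4882 to 6359, 8265 to 9152 and 8552 to 9122 for AZD6738+IR against IR, AZD6738 and DMSO, and 3152 to 4559 for the interaction. The lone library then left in a group was assumed to vary like the other groups. The planned fit with the replicate numbers of the labels as a block was not run, because the value columns carry letters and not those numbers. Nothing says that a letter marks libraries prepared together, and across loci the differences between B and A correlated between groups with r from -0.05 to 0.16. With the letter as a replicate block 13 loci passed for AZD6738 against DMSO, 7895 for IR against DMSO, 6524, 9252 and 9300 for AZD6738+IR against IR, AZD6738 and DMSO, and 4445 for the interaction. Depth is unknown, so counting error could not be set against the spread between libraries.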

Other observations

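The camera tests in this part, the description of translation factors and the results of the amino acid list in comparisons other than IR against DMSO were chosen after results were seen, while the other tests used lists and bounds written before. Beyond the genes named so far, irradiation lowered transporters, tRNA ligases and one-carbon enzymes known to be induced when amino acids run short. Compared with DMSO, IR had SHMT2 at 46.5 against 162 FPKM, MTHFD2 at 35.2 against 109, GARS at 65.4 against 165, EPRS at 102 against 232, XPOT, which exports tRNA from the nucleus, at 22.6 against 62.4, and the amino acid transporters SLC7A5 at 103 ± 2.2 against 226 ± 27 and SLC1A5 at 43.3 against 114. Of 24 such genes 23 fell and none rose, and 17 fell further in AZD6738+IR than in IR. For AZD6738+IR against IR, these genes had camera adjusted p = 1.71e-05 as a list, and 0.236 with an estimated correlation. With AZD6738 alone none of the 24 passed singly. Their median of 0.16 was at or above that of all 10000 abundance-matched random lists, which take genes as independent, but camera adjusted p = 0.268 with an estimated correlation of 0.49.

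Among mRNAs with a terminal oligopyrimidine tract outside the list of ribosomal protein genes, 15 of 21 fell with irradiation alone, by a median of -0.43 for the list, and all 21 fell when AZD6738 was added to it, by a median of -0.71. The 21 still included FAU, which encodes a ribosomal protein, and GNB2L1, which encodes a protein bound to the ribosome. EEF2 had means of 1718, 1677, 1273 and 515 FPKM in DMSO, AZD6738, IR and AZD6738+IR, EEF1A1 had 1019, 1059, 973 and 511, EEF1B2 had 527, 522, 482 and 199, and EIF4B had 271, 243, 165 and 64.8. The nucleolar protein gene NPM1 had 1534, 1421, 686 and 398. For 7 of the 21, NPM1, HNRNPA1, NACA, BTF3, EIF3A, EIF3D and EIF3G, the fall with irradiation was at least as large as that on adding AZD6738, and this difference was not tested. With an estimated correlation the list had camera adjusted p = 0.225 for irradiation alone and 0.099 on adding AZD6738. In limma's fit, the log2 fold changes of AZD6738+IR against IR were -1.3 for EEF2, -0.93 for EEF1A1, -1.27 for EEF1B2 and -1.33 for EIF4B.

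The fall of amino acid synthesis genes after radiation, seen in ASNS and PSAT1, was tested on the 24 further genes of the amino acid response. Their median in IR against DMSO was -1.06, with 0 of 10000 abundance-matched random lists at or below it, and -0.99 or lower under each other scaling, so scaling alone does not account for it, though camera adjusted p = 6.51e-08 became 0.225 with an estimated correlation. A fall of stress genes of every kind was tested on 12 genes of a list of endoplasmic reticulum chaperones, not all of them chaperones. Members of the earlier lists were left out. Their median of -0.15 lay at percentile 33.7 of such lists, which argues against such a fall for this set alone. Of the 12, 5 were lower and 2 higher, among the latter CALR at 338 against 211 FPKM. Other kinds of stress genes were not tested in this way. Lower activity of the amino acid response after irradiation may account for the fall, as a hypothesis found and tested on the same data. Most ribosomal protein and cell cycle genes fell in the same comparison, and whether these falls are related was not tested. Cell density and the amino acids left in the medium after 3 days were not tested and stay open, since dividing cultures without irradiation could have used up more of them.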
